A study of Mus musculus with 15 samples.

How the data were processed

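Bulk liver RNA was sequenced on an Illumina instrument from mice started at 8 weeks of age, per the labels' protocols. The study arms held 10 Chow mice and 15 mice in each injected arm; 15 samples are described, and 14 were analysed. Chow replicate 5 was not analysed here, so Chow has 4 libraries and each fit holds 14 libraries instead of the 15 planned. The diet was given for 12 weeks before injections began. The vehicle held 15% Kolliphor. The labels do not say whether Chow mice were injected, so the diet and the injections cannot be separated, and they give no time of day for collection.

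Total counts were 29950509 or more in every library. The deposited table holds raw counts per Ensembl gene identifier, 1 column per library, without normalization. Reads were aligned with STAR 2.7.11b to GRCm39, per the submitters' processing notes. The counting tool, the annotation release and the strand setting are not given in the sources used here; overlapping and antisense genes and members of families of similar sequence are therefore uncertain. Gene symbols came from a reference table of an earlier assembly, used for names only, and matched 51880 identifiers (90.8%) holding 99.6% of counts. Bmal1 is listed there as Arntl.

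Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group (minimum count 10, minimum total 15), which left 18181 genes with 99.9% of counts. Libraries were scaled by TMM, with factors from 0.753 to 0.824 in Chow and from 1.02 to 1.15 in diet-fed libraries. Dispersions and quasi-likelihood fits were robust, all groups shared 1 estimate of the spread, and p-values were adjusted by Benjamini-Hochberg over all tested genes with a threshold of 0.05. Standard errors of log2 fold changes are those that give the quasi-likelihood F. CPM values use the TMM-scaled totals, except the floor of 3 counts, which uses raw totals. The common coefficient of biological variation was 0.211. Floors and counting precision cover counting error only.

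Before the data were examined, 46 gene lists of liver functions, cell types, contaminants and stress responses were fixed, as were the tests, the alternatives and the rule for named genes. Lists were tested with camera in limma 3.58.1, two-sided, with a preset correlation of 0.01, adjusted over the 46 lists. With an estimated correlation 1, 4 and 1 lists were called in Vehicle versus Chow, SR9009 versus Vehicle and SR9009 versus Chow. The monocyte and lipid macrophage list was called in the first and last. In the second, those called were drug metabolism, oxidative stress, clock, and feeding and insulin responsive genes. The rule named 7 genes always (Nr1d1, Nr1d2, Bmal1, Col1a1, Col3a1, Acta2 and Timp1). It added the 5 largest rises and 5 largest falls among called genes with at least 5 CPM in the higher group and no overlap between libraries, leaving out predicted and immunoglobulin genes. It also added up to 4 members of each described list with the smallest adjusted p, and up to 5 genes per direction with opposite calls under diet and SR9009. SR9009 versus Chow names only genes named in the other comparisons. A result for 1 gene that the rule names is not reported here.

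List scores are means of log2 CPM over tested members, compared between SR9009 and Vehicle by exact two-sided permutation tests whose smallest p is 0.00794; they were added after seeing the data. Within groups, the 26 library pairs differed by far more than sampling noise (lowest mean chi-square per gene 15.7), so none was counted as a repeat. The number of olfactory, vomeronasal and trace amine receptor genes with a count, out of 1985, parted the libraries: from 50 to 113 in all 4 Chow, 2 Vehicle and 2 SR9009 libraries, and from 158 to 243 in 3 Vehicle and 3 SR9009 libraries. This class was seen only in the data and used in added alternatives. Its boundary of 113.8 was set from the diet-fed libraries. Chow replicate 1, at 113, fell just below that boundary, while the other Chow libraries had 50 to 56. On the second principal component Chow replicate 1 was at 45.1, on the side of the libraries with many receptor genes, so its class is uncertain.

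The pipeline was tested on simulated counts for 18181 genes. For SR9009 versus Vehicle it recovered 39.3%, 66.7% and 90.4% of genes changed by 1.5, 2 and 4-fold, with 5.15% of calls false. Alternatives were DESeq2 1.42.0, limma-voom with quality weights, DESeq2 size factors, other filters, only the groups compared, a replicate block, other set tests and leaving out each library.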

Results

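Liver RNA was sequenced from male C57BL/6J mice, a common inbred laboratory strain, in 3 groups. Chow mice ate standard chow. Vehicle and SR9009 mice ate a choline-deficient, amino-acid-defined high-fat diet, which produces steatohepatitis and fibrosis in mice, for 18 weeks. In the last 6 of those weeks they received daily intraperitoneal injections, either of vehicle or of SR9009 at 100 mg/kg per day. SR9009 is a synthetic agonist of the nuclear receptors REV-ERB alpha and beta, the products of Nr1d1 and Nr1d2, which repress transcription within the circadian clock. The analysis used 4 Chow, 5 Vehicle and 5 SR9009 libraries, each from a separate mouse. Total counts per library ranged from 29950509 to 45542335. On these raw totals a floor of 3 counts corresponded to between 0.0659 and 0.10 CPM (counts scaled to a common library total). The other CPM values use TMM-scaled totals. On that scale the floor is higher in Chow, where the factors were 0.753 to 0.824. It is lower in diet-fed libraries, where they were 1.02 to 1.15. Of 57132 gene identifiers, 18181 passed the expression filter and were tested. The first principal component held 66.6% of the variance and separated Chow from diet-fed libraries, while Vehicle and SR9009 libraries overlapped on it.

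**Figure D1:**
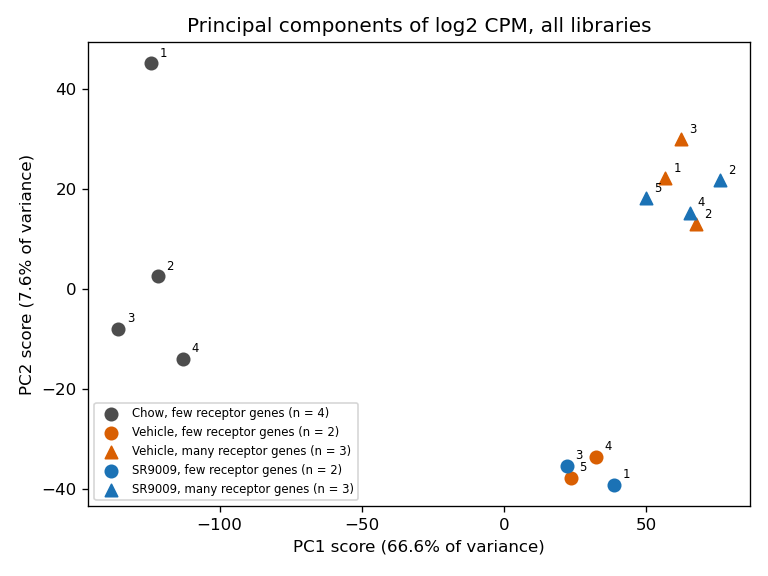
Scores of the 14 libraries on the first and second principal components of log2 CPM, in arbitrary units, with the replicate number beside each point. Colour gives the group, and triangles mark libraries in which many olfactory, vomeronasal and trace amine receptor genes had a count; PC2 holds 7.6% of the variance and parts the diet-fed libraries by that mark, with Vehicle and SR9009 libraries on both sides.

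The comparison of Vehicle with Chow asked what the diet, together with vehicle injections, did to the liver. Macrophage, scar matrix and inflammatory genes were higher and many hepatocyte genes lower in Vehicle livers. Gpnmb, a glycoprotein of lipid-laden macrophages, was at 601 ± 136 CPM (SD, n = 5) in Vehicle and 0.144 ± 0.0328 CPM (SD, n = 4) in Chow. Mmp12, the macrophage elastase, was at 301 ± 47.4 CPM against 0.351 ± 0.146 CPM. Col1a1 (ENSMUSG00000001506.11), the main fibrillar collagen chain of scar tissue, was 18.7-fold higher (log2 fold change 4.23 ± 0.32 SE, adjusted p = 1.19e-07), and Col3a1 was 11.1-fold higher (3.48 ± 0.27, adjusted p = 1.18e-07). Over all genes, 10035 were called, 5414 higher and 4621 lower in Vehicle, and 4853 of them changed at least 2-fold.

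Most fibrosis genes rose. In the fibrillar collagen and matrix list, 27 of 28 members rose and 1 fell, with a median log2 fold change of 2.57 (camera adjusted p = 3.75e-17; adjusted p = 0.197 with an estimated correlation). Thbs1, encoding the matricellular protein thrombospondin, was 35.6-fold higher, and the proteoglycan gene Dcn was 3.01-fold higher. In the matrix remodelling list 26 of 28 members rose and 1 fell (adjusted p = 4.2e-18; adjusted p = 0.101 with an estimated correlation). Timp1, an inhibitor of matrix metalloproteases, was 57.1-fold higher and the protease gene Plau 11.1-fold higher. Among 19 myofibroblast markers 14 rose and 1 fell (adjusted p = 1.78e-06; adjusted p = 0.203 with an estimated correlation). Acta2, the smooth muscle actin of activated stellate cells, was 3.95-fold higher, Spp1 12.5-fold higher and Tgfb1 3.26-fold higher. Adjusted over the list alone, 27 fibrillar, 27 remodelling and 14 myofibroblast genes rose and 1 of each list fell.

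Immune, ductal and cell cycle genes rose as well. Of 25 monocyte and lipid macrophage markers 22 rose and none fell, and this list alone kept its call with an estimated correlation (adjusted p = 0.023). Clec7a was 30.5-fold and Capg 22.3-fold higher. Kupffer cell markers, those of the resident macrophages, went both ways: 2 of 15 rose and 4 fell, and the list was not called (adjusted p = 0.225). Cd163 fell by 5.13 on the log2 scale (SE 0.46, adjusted p = 3.58e-07) and Timd4 fell by 3.19 (SE 0.52, adjusted p = 9.86e-05). Among 27 cytokine and chemokine genes 22 rose and 2 fell (adjusted p = 3.55e-10; adjusted p = 0.101 with an estimated correlation). The monocyte co-receptor gene Cd14 was 17.5-fold higher, and Ccl22 was at 3.36 ± 0.595 CPM in Vehicle and 0.0278 ± 0.0343 CPM in Chow. Of 22 inflammasome and innate sensor genes, 20 rose and 1 fell (adjusted p = 2.21e-08; adjusted p = 0.216 with an estimated correlation). Of 21 cholangiocyte markers, 20 rose (adjusted p = 6.05e-08; adjusted p = 0.241 with an estimated correlation), among them Cldn4 at 23.2-fold. Of 28 cell cycle genes, 26 rose (adjusted p = 2.91e-12; adjusted p = 0.203 with an estimated correlation), among them Mki67, a marker of proliferating cells, at 12.0-fold. Adjusted over the list alone, 22 macrophage, 22 cytokine, 20 inflammasome, 20 cholangiocyte and 27 cell cycle genes rose, and 2 cytokine and 1 inflammasome gene fell; of the Kupffer markers 2 rose and 3 fell.

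Several lists of hepatocyte genes were lower, while others were not called: fatty acid oxidation (9 of 28 members higher, 11 lower; adjusted p = 0.543), gluconeogenesis and glycolysis (5 of 23 higher, 13 lower; adjusted p = 0.17, but called lower without the low-count filter) and acute phase (6 of 23 higher, 6 lower; adjusted p = 0.827). Of 24 fatty acid synthesis genes 19 fell and 2 rose (adjusted p = 4.42e-09; adjusted p = 0.203 with an estimated correlation), and Scd1, the stearoyl-CoA desaturase, went from 12753 ± 2889 CPM to 574 ± 198 CPM. Phosphatidylcholine and methyl metabolism, the pathway that the diet's lack of choline bears on, had 19 of 24 members lower and 2 higher. Its adjusted p was 2.23e-07, and 0.203 with an estimated correlation, and Gnmt fell by 1.74 on the log2 scale. The median of this list was -0.82. Medians were -1.66 for fatty acid synthesis, -0.83 for bile acid, -0.77 for secreted marker and -0.58 for oxidative phosphorylation genes. The fall was therefore not particular to this pathway. Bile acid genes had 16 of 23 members lower and 2 higher (adjusted p = 4.23e-06; adjusted p = 0.203 with an estimated correlation); the bile salt transporters Slc10a1 and Abcb11 fell by 2.01 and 1.30. Of 29 oxidative phosphorylation genes 28 fell (adjusted p = 5.27e-08; adjusted p = 0.349 with an estimated correlation), including Sdha, which fell by 0.76. Of 27 hepatocyte secreted markers 21 fell (adjusted p = 4.78e-08; adjusted p = 0.216 with an estimated correlation). The urea cycle gene Cps1 fell by 1.63. Adjusted over the list alone, 20 fatty acid synthesis, 19 phosphatidylcholine, 16 bile acid, 28 oxidative phosphorylation and 22 secreted marker genes fell, and 2 of each of the first 3 lists rose. Vehicle replicate 2 lay below the other Vehicle libraries for Slc10a1 and Abcb11.

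Genes that differ between male and female livers also moved. All 21 tested genes of the male-biased list were lower in Vehicle (adjusted p = 3.54e-10; adjusted p = 0.216 with an estimated correlation), with Hsd3b5 at 0.843 ± 1.37 CPM against 438 ± 152 CPM in Chow and Elovl3 falling by 4.65. Of 12 female-biased genes, 10 rose (adjusted p = 0.0219; adjusted p = 0.481 with an estimated correlation), including Cyp2b9, which rose by 5.73 on the log2 scale (6.82 without Chow replicate 2), and Cyp2a4, which was at 34.1 ± 63.5 CPM with 1 Vehicle library at 148 CPM. The major urinary protein genes Mup7, Mup15 and Mup17 were among the largest falls; they are near-identical copies, so their separate values are uncertain. Moxd1 and Trhde were also among the largest falls, although Moxd1 varied from mouse to mouse in Chow (70.5 ± 114 CPM) and Trhde was at 8.89 ± 1.51 CPM in Chow. Mmp7 and the vomeronasal receptor gene Vmn2r3 were among the largest rises, at 14.8 ± 7.26 and 18.1 ± 7.39 CPM in Vehicle. Of 23 clock and REV-ERB target genes 12 fell and 3 rose (adjusted p = 0.0232; adjusted p = 0.216 with an estimated correlation). Nr1d1 fell by 0.76 (SE 0.16, adjusted p = 0.000662), and Hlf and Clock fell by 1.18 and 0.59. Nr1d2 (adjusted p = 0.0622) and Arntl, which encodes BMAL1 (adjusted p = 0.274), did not pass; Nr1d2 passed without Chow replicate 1 (adjusted p = 0.026) or Vehicle replicate 2 (0.022) or 5 (0.0401). Of 26 drug metabolism genes 14 fell and 6 rose (adjusted p = 0.00238; adjusted p = 0.163 with an estimated correlation), and Cyp2c29 fell by 4.27. The median of this list was -0.59 but its mean 0.14. Adjusted over the list alone, 21 male-biased genes fell and 10 female-biased genes rose, 13 clock genes fell and 4 rose, and 14 drug metabolism genes fell and 6 rose.

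The comparison of SR9009 with Vehicle asked what the REV-ERB agonist changed in diet-fed livers. Drug metabolism genes rose. Cyp2b10 (ENSMUSG00000030483.15), a cytochrome P450 known as a target of the receptor CAR, was at 437 ± 91.8 CPM (SD, n = 5) in SR9009 and 0.386 ± 0.479 CPM (SD, n = 5) in Vehicle, a log2 fold change of 10.17 ± 0.69 SE (adjusted p = 1.12e-05) that was 11.18 without Vehicle replicate 2. Cyp2c29 rose by 5.90 ± 0.22 (adjusted p = 2.03e-10), from 81.1 ± 23.8 to 4859 ± 549 CPM. The clock genes Arntl and Npas2 fell, Arntl from 23.1 ± 3.56 to 8.16 ± 4.07 CPM (adjusted p = 0.0482) and Npas2 by 1.72 ± 0.31 (adjusted p = 0.0341). The collagen genes Col1a1 and Col3a1 were not called. In total 44 genes were called, 30 higher and 14 lower in SR9009, 20 of them at least 2-fold, and 1323 genes had an unadjusted p under 0.05.

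**Figure D2:**
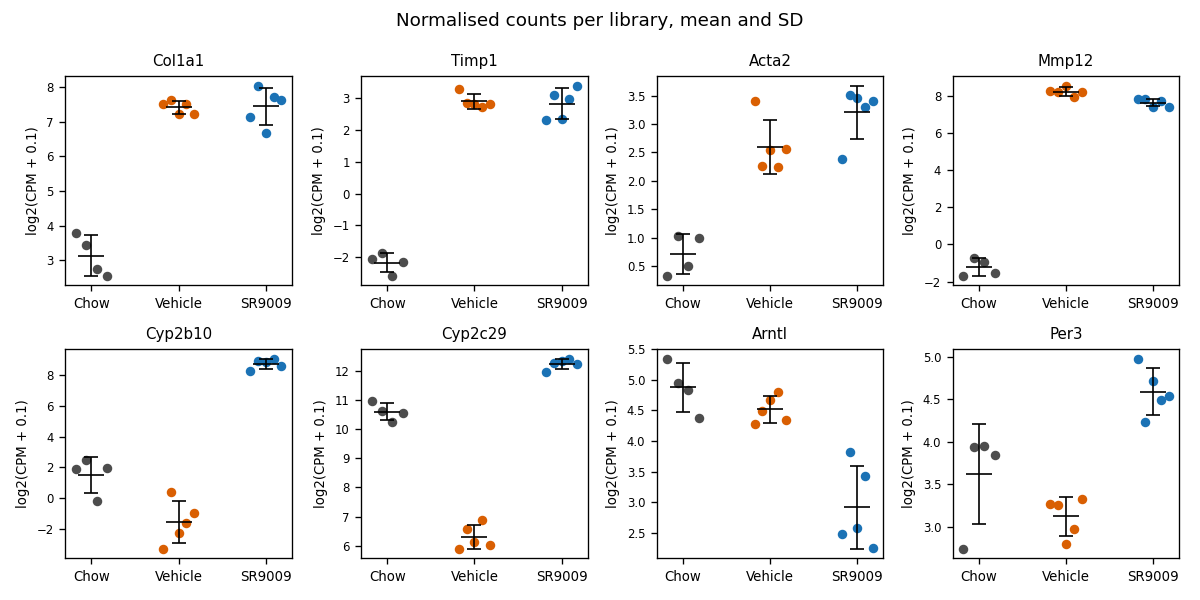
Normalised counts of 8 genes as log2(CPM + 0.1), 1 point per library, with the mean and SD of each group of 4 Chow, 5 Vehicle and 5 SR9009 libraries; axes do not start at 0. Col1a1 and Timp1 overlap between Vehicle and SR9009, while Cyp2b10 and Cyp2c29 are higher and Arntl lower in every SR9009 library than in any Vehicle library.

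Of 26 tested drug metabolism genes, 9 rose and none fell over all genes tested, and 17 rose when adjusted over the list alone. The list was called (camera adjusted p = 1.52e-83) and stayed so with an estimated correlation (adjusted p = 1.48e-07). Cyp2c55 rose by 4.13 ± 0.19 and Cyp2c37 by 1.94 ± 0.14. The carboxylesterase gene Ces2a, outside this list, rose by 2.26 ± 0.22. Por, which encodes the electron donor of microsomal P450 enzymes, and Cyp3a11 were named after their values were seen; they rose by 0.67 ± 0.11 and 1.23 ± 0.13, and the call of Por was lost in 2 of 14 fits without 1 library (adjusted p up to 0.0531). The Cyp2b, Cyp2c, Cyp3a and Gst genes belong to families of similar sequence, and how the authors' counting split shared reads is not given in the sources used here. The mean log2 CPM over the list was 1.58 higher in SR9009 (95% interval 1.40 to 1.76), with all 5 SR9009 libraries above every Vehicle library; the exact permutation test gave p = 0.00794, the smallest it can give, and 0.073 after adjustment over 46 lists. Within the libraries that had few and many receptor genes detected the differences were 1.51 and 1.63.

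Of 26 genes of the oxidative stress list, 6 rose, and 9 adjusted over the list alone (adjusted p = 4.09e-21; adjusted p = 0.00332 with an estimated correlation). Those were Gstm1, Gstm2, Gstm3, Gsta1, Gsta4 and Ces2a, conjugating and hydrolysing enzymes. Gstm3 rose by 1.54 ± 0.16, Gstm1 by 0.92 ± 0.13 and Gstm2 by 0.87 ± 0.12. Cyp1a2, a P450 of pericentral hepatocytes, rose by 1.45 ± 0.27 (adjusted p = 0.0373), a call lost in 12 of the 14 fits that left out 1 library (adjusted p up to 0.114), all but those without Vehicle replicate 2 or 5. The list of 18 pericentral markers, which shares Cyp2c29 and Cyp1a2 with the drug metabolism list, was called higher (adjusted p = 1.25e-11; adjusted p = 0.25 with an estimated correlation) with 3 members higher, and 4 higher and 1 lower adjusted over the list alone. Its median was 0.12 and, without Vehicle replicate 2, -0.0308. That library lay below the other Vehicle libraries for Ces2a, Cyp1a2 and Cyp2c50, the last named after its values were seen, and without it Cyp1a2 rose by 1.23 (adjusted p = 0.000125).

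Among 23 clock and REV-ERB target genes, 3 rose and 2 fell over all genes, and 11 rose and 6 fell when adjusted over the list alone. The list was called higher (adjusted p = 1.06e-07; adjusted p = 0.0117 with an estimated correlation). Per3, a period gene, rose by 1.48 ± 0.20 (adjusted p = 0.00406), Usp2 by 1.23 ± 0.18 (adjusted p = 0.00508) and Tef by 0.86 ± 0.16 (adjusted p = 0.0373). Dbp, named after its value was seen, had a log2 fold change of 1.69 ± 0.32 and an adjusted p of 0.0537, and 0.0194 without Chow replicate 1. Nr1d1 and Nr1d2 were not called, at 0.29 ± 0.15 (adjusted p = 0.734) and 0.40 ± 0.13 (adjusted p = 0.388). The list score was 0.29 higher in SR9009 (95% interval 0.13 to 0.45; exact permutation p = 0.00794, the smallest possible, 0.073 adjusted), and 0.27 and 0.30 higher within the libraries with few and many receptor genes. The calls of Arntl, Npas2 and Tef were lost in 11, 7 and 10 of the 14 fits that left out 1 library, Chow libraries included, with adjusted p up to 0.129, 0.119 and 0.114. Arntl kept its call without SR9009 replicate 2 or Chow replicate 1 or 4. Npas2 kept its call without SR9009 replicate 2, Vehicle replicate 2 or 5, or any 1 Chow library, and Tef without SR9009 replicate 2, Vehicle replicate 5 or Chow replicate 1 or 2.

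The calls of the fibrosis lists under SR9009 depended on the fit. Of 28 fibrillar collagen and matrix genes 0 were called in edgeR, 0 adjusted over the list alone, 0 at an unadjusted p under 0.05 and 0 in DESeq2. Of 28 matrix remodelling genes 0 were called in edgeR, while 1 was lower adjusted over the list alone, 2 were lower at an unadjusted p under 0.05 and 1 was lower in DESeq2. The lists were not called (adjusted p = 0.186 and 0.725; adjusted p = 0.872 and 0.914 with an estimated correlation); the remodelling median was 0.03 and its test pointed lower. The fibrillar list was called higher without Vehicle replicate 2 (median 0.15, adjusted p = 0.0344) and without SR9009 replicate 3 (0.23, adjusted p = 0.000371). These calls, and those below within receptor gene classes or with added terms, used camera at the preset correlation of 0.01. The correlation estimated for the fibrillar list with all libraries was 0.444. These fits were not run with an estimated correlation, so their calls cannot show a rise or fall of the list. Col1a1 was at 184 ± 63.1 CPM in SR9009 and 172 ± 22.5 CPM in Vehicle, a ratio of 1.07 with a 95% interval of 0.737 to 1.55. For Col3a1 the ratio was 1.15 (0.821 to 1.60) and for Timp1 0.983 (0.729 to 1.33). Acta2 had a ratio of 1.52 (1.05 to 2.18; adjusted p = 0.58), with Vehicle replicate 1 above and SR9009 replicate 1 below the rest of their groups. Sparc had a ratio of 1.25 (0.940 to 1.65). The fibrillar list score differed by 0.08 (95% interval -0.37 to 0.54; exact permutation p = 0.706) and the matrix remodelling score by -0.01 (-0.42 to 0.41; exact permutation p = 0.96). These scores were 0.47 and 0.43 lower in diet-fed libraries with few receptor genes than in those with many. The fibrillar median was -0.16 (adjusted p = 0.602) within the first kind and 0.23 (adjusted p = 0.00906) within the second. With red cell and mesothelial scores as terms, an alternative chosen after seeing the data, the fibrillar and remodelling lists were called lower. Their medians were -0.21 (adjusted p = 0.0378) and -0.29 (adjusted p = 0.00815). The red cell and mesothelial scores were themselves 0.73 and 1.21 higher in SR9009 than in Vehicle (exact permutation p = 0.23 and 0.0476, unadjusted). Efemp1 belongs to both the mesothelial and the fibrillar list. Terms that move with the treatment can shift its fitted effect, so this fit cannot show whether SR9009 lowered matrix genes.

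**Figure D3:**
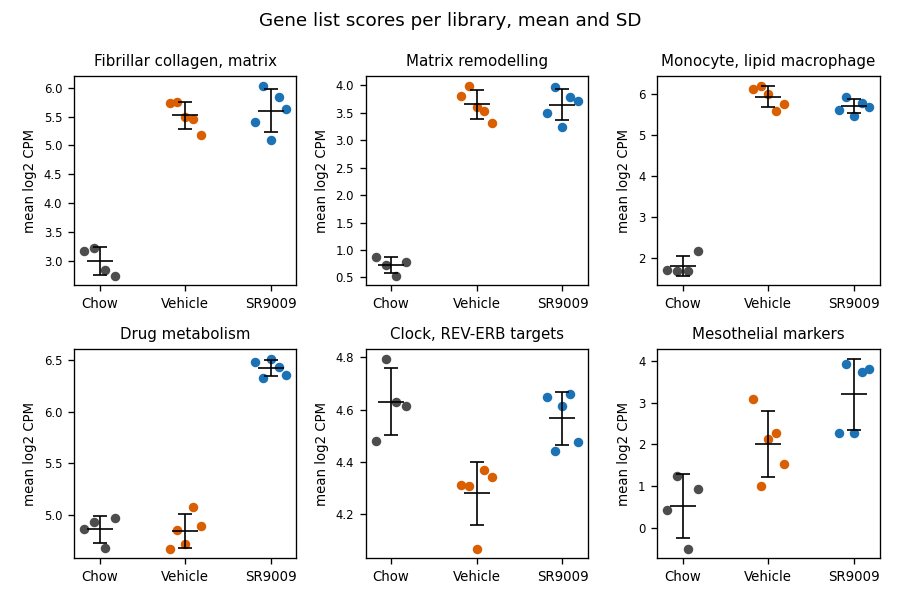
Mean log2 CPM over the members of 6 gene lists, 1 point per library, with the mean and SD of 4 Chow, 5 Vehicle and 5 SR9009 libraries; axes do not start at 0. Fibrillar collagen and matrix remodelling scores overlap between Vehicle and SR9009, and all 5 SR9009 libraries lie above every Vehicle library for drug metabolism and for clock genes.

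Myofibroblast markers were not called (adjusted p = 0.181, and 0.768 with an estimated correlation). At the preset correlation they were called higher without SR9009 replicate 1 (adjusted p = 0.0237) or 3 (adjusted p = 0.0181). Cytokines and chemokines (adjusted p = 0.729) and inflammasome genes (adjusted p = 0.214) were not called. Stellate cell markers were called higher (adjusted p = 0.00242; adjusted p = 0.259 with an estimated correlation), with 0 of 19 members called in edgeR, 1 higher adjusted over the list alone, 5 higher at an unadjusted p under 0.05 and 1 higher in DESeq2. Monocyte and lipid macrophage markers were called lower, with a median of -0.26 (adjusted p = 3.45e-06; adjusted p = 0.259 with an estimated correlation). Of its 25 members 0 were called in edgeR, while 2 were lower adjusted over the list alone, 7 at an unadjusted p under 0.05 and 2 in DESeq2. Within libraries with few receptor genes this list was not called (adjusted p = 0.0738). Mmp12 had a log2 fold change of -0.60 ± 0.13 (adjusted p = 0.108). Mesothelial markers had a median of 1.10 (adjusted p = 1.14e-05; adjusted p = 0.277 with an estimated correlation), with Msln at 21.7 ± 12.2 CPM in SR9009 and 7.79 ± 5.92 CPM in Vehicle, and Muc16 at 8.81 ± 5.81 and 1.67 ± 1.58 CPM. The mesothelial score differed by 0.38 within libraries with few receptor genes, where the list was not called (adjusted p = 0.71), and by 1.76 within those with many, with SR9009 replicates 2, 4 and 5 above every Vehicle library and replicates 1 and 3 within their range.

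Metabolic lists had small medians. Feeding and insulin responsive genes were called lower (camera adjusted p = 0.000231, and 0.0411 with an estimated correlation), although 8 of 20 members had log2 fold changes above 0. In edgeR 0 of 20 members were called over all genes and 4 fell adjusted over the list alone. At an unadjusted p under 0.05, 7 were lower, and 3 fell in DESeq2. G6pc, the glucose-6-phosphatase gene, had a log2 fold change of -1.63 ± 0.39, Pck1 of -0.79 ± 0.21 and Cpt1a of -0.36 ± 0.08 (adjusted p = 0.163, 0.225 and 0.11). Cholesterol biosynthesis genes were called higher with a median of 0.39 and 11 of 25 members higher adjusted over the list alone (adjusted p = 7.02e-17; adjusted p = 0.252 with an estimated correlation); Dhcr7 was at 0.64 ± 0.20 (adjusted p = 0.324). Fatty acid oxidation genes (adjusted p = 3.17e-06; adjusted p = 0.259 with an estimated correlation) and lipid droplet genes (adjusted p = 0.000713; adjusted p = 0.259 with an estimated correlation) were called lower, with 2 members of each lower adjusted over the list alone, and Plin2 was at -0.58 ± 0.14. The fatty acid oxidation score differed by -0.03 within libraries with few receptor genes and by -0.36 within those with many, and the lipid droplet score by -0.10 and -0.39; neither list was called within the first kind (adjusted p = 0.646 and 0.62). Adipocyte markers were also called lower (adjusted p = 0.0338; adjusted p = 0.25 with an estimated correlation), a call lost in 4 of 14 fits without 1 library (adjusted p up to 0.11): those without Vehicle replicate 2 or 5 or SR9009 replicate 1 or 2. Their score differed by -0.45, with all 5 SR9009 libraries below every Vehicle library (exact permutation p = 0.00794, the smallest possible, 0.073 adjusted). Bile acid genes were called higher (adjusted p = 0.0277; adjusted p = 0.606 with an estimated correlation), with Cyp7a1 and Abcc4 at 1.18 ± 0.30 and 1.13 ± 0.25, neither called; Abcc4 was called without Vehicle replicate 2 (adjusted p = 0.00801). That list call was lost without Vehicle replicate 1, 2 or 3 or SR9009 replicate 1 or 3 (5 of 14 fits, adjusted p up to 0.289). Phosphatidylcholine and methyl metabolism genes were called lower (adjusted p = 0.0234; adjusted p = 0.606 with an estimated correlation). That call was lost without Vehicle replicate 4 or 5 or SR9009 replicate 2 or 4 (4 of 14 fits, adjusted p up to 0.287). Chka, the choline kinase, was the called member and fell by 1.38 ± 0.21 (adjusted p = 0.00935). Immediate early genes were called lower (adjusted p = 5.31e-06; adjusted p = 0.259 with an estimated correlation), with Nr4a1 and Btg2 at -2.33 ± 0.78 and -1.22 ± 0.38, neither called; Nr4a1 was at -1.35 without Vehicle replicate 4. The bile acid, phosphatidylcholine, adipocyte and immediate early lists were not called within libraries with many receptor genes. Nor were the phosphatidylcholine and adipocyte lists within those with few. Bile acid scores differed by 0.09 within few and 0.14 within many, against 0.12 across all, and phosphatidylcholine scores by -0.15 and -0.13, against -0.14. These 2 differences stayed about as large in the smaller groups. Adipocyte scores differed by -0.66 and -0.31, against -0.45, and immediate early scores by -0.94 and -0.28, against -0.55. The list of feeding and insulin responsive genes was not called with red cell and mesothelial terms (adjusted p = 0.212). Arl4a fell by 0.93 ± 0.17 (adjusted p = 0.0423), a call lost in 10 of 14 fits without 1 library (adjusted p up to 0.138).

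The number of genes called under SR9009 depended on the method and on single libraries. DESeq2 called 206. In fits chosen after seeing the data, 78 were called with the receptor gene class as a term. Within libraries with few and many receptor genes, 10 and 21 were called. These fits compare only 2 and 3 libraries per group, so their lower counts cannot be read as an effect of the class. Calls numbered 27, 56, 21 and 26 without Vehicle replicate 1, 2, 3 or 4, and 20, 25, 18 and 19 without SR9009 replicate 1, 3, 4 or 5.

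The overlap of the diet and SR9009 calls asked whether SR9009 moved genes back towards Chow. In total 21 genes had opposite calls and 9 had calls in the same direction. Of the opposite calls, 18 were lower with the diet and higher with SR9009, against 7.62 for independent lists, and they included Cyp2c29, Cyp2c55, Cyp2c37, Cyp2b10 and Ces2a. The other 3 were higher and then lower, against 4.17 for independent lists: Rnf144a, Gpc1 and Prph, the last named after its values were seen. Rnf144a fell by 1.05 ± 0.18 under SR9009 and Gpc1, a cell surface proteoglycan, by 0.72 ± 0.13. Slc13a3 rose in both comparisons, by 1.78 and 0.62. The calls of Gpc1, Slc13a3 and Rnf144a under SR9009 were lost in 9, 10 and 6 of the 14 fits without 1 library. Of the 18 genes, 7 ended above Chow, 4 below and 7 were not called against Chow. The Vehicle libraries serve in both comparisons. Splitting the Vehicle libraries between the comparisons gave a median of 9 opposite calls (6 to 22 over 20 splits), where only a median of 18 genes (7 to 58) were called under SR9009. Across genes, which are not independent replicates, the fold changes had a Pearson r of -0.082 and a Spearman rho of -0.042. Simulations with no effect gave medians of -0.033 and -0.010. The covariance was -0.041, with a simulated median of -0.011. The simulated SR9009 libraries were drawn around the observed Vehicle means. They leave out the error that both comparisons share through the Vehicle libraries, so no conclusion is drawn from them. The jackknife standard error of r, from leaving out 1 library at a time, was 0.254. With the Vehicle libraries split, r had a median of 0.0085 and ranged from -0.192 to 0.340. It was -0.312 with DESeq2, 0.0016 without Vehicle replicate 2 and 0.0404 without SR9009 replicate 3. Opposite calls numbered 11 without Vehicle replicate 3, and 12, 13, 10 and 11 without SR9009 replicate 1, 3, 4 or 5.

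The comparison of SR9009 with Chow asked how far treated livers stayed from chow livers. Macrophage and scar genes remained far above Chow. Col1a1 was higher by 4.32 ± 0.32 and Col3a1 by 3.67 ± 0.28 on the log2 scale. Of 28 fibrillar matrix genes 27 were higher and 1 lower (adjusted p = 1.11e-17; adjusted p = 0.23 with an estimated correlation), and 22 of 25 monocyte and lipid macrophage markers were higher (adjusted p = 3.45e-36; adjusted p = 0.0334 with an estimated correlation). Cyp2b10 was 7.02 ± 0.65 and Cyp2c29 1.64 ± 0.19 above Chow, Ces2a was 1.58 ± 0.22 below it, and Cyp2c37 was not called (0.05 ± 0.14, adjusted p = 0.762). Arntl, Npas2 and Chka were lower than in Chow, by log2 fold changes of -1.89, -1.96 and -1.18. Of 23 clock genes 9 were higher and 10 lower, and the list was not called (adjusted p = 0.319). Drug metabolism genes had 13 of 26 members higher and 4 lower, without a call of the list (adjusted p = 0.114), which among the fits that left out 1 library was called, as higher, without Vehicle replicate 2 alone (adjusted p = 0.0429). In total 10213 genes were called, 5548 higher and 4665 lower.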

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

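All tests in this part were chosen after the results were seen, the splits of the libraries included, except those on library depth and on other silent genes. Of 354 groups of 4 or 5 libraries examined, 30 held a library far from the rest of its group. Chance alone gives about 1 group in 20 for independent, normally distributed values. Genes measured in the same library are not independent, and in some flagged groups all other libraries had no count. The 30 groups therefore cannot be weighed against that rate.

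Vehicle replicate 2 accounted for 11 of the flagged groups. Its Cyp2a4 was at 147.6 CPM (2.74 to 7.95 in the other Vehicle libraries) and its female-biased and fetal and tumour list scores at 4.131 (1.79 to 2.40) and 3.659, while Elovl3 was at 5.412, Slc10a1 at 113.7, Abcb11 at 337.4, Ces2a at 18.61, Cyp1a2 at 149.7 and Cyp2c50 at 108.2 CPM, each below the other Vehicle libraries. Its Abcc4 was at 24.38 CPM, above them, and Trhde at 0.0706 CPM, where the others had no count. Without this library 56 genes were called for SR9009 versus Vehicle.

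Other libraries stood apart for single values. Vehicle replicate 1 was high for Acta2 (10.47 CPM) and Timp1 (9.672 CPM). SR9009 replicate 1 was low for Acta2 (5.132 CPM) and high for Cyp2a4 (40.49 CPM). Chow replicate 1 was low for Per3 (6.596 CPM), high in receptor genes detected (113), and the only Chow library with a count for Vmn2r3 (0.0702 CPM) or Mmp7 (0.2105 CPM). Vehicle replicate 5 was low for Gpc1 (35.83 CPM) and the myofibroblast score (3.705), and Vehicle replicate 3 for the clock score (4.066). Mup7 was high in SR9009 replicate 3 (13.8 CPM), Btg2 in SR9009 replicate 4 (48.61 CPM) and Trhde in SR9009 replicate 5 (0.0237 CPM). That Trhde value and the Vmn2r3 value of Chow replicate 1 were below the floor of 3 counts. Cyp2c37 was low in Chow replicate 3 (325.9 CPM), Dhcr7 low in Chow replicate 2 (109.7 CPM), and the macrophage, T and NK cell, and B and plasma cell scores high in Chow replicate 4 (2.192, -0.8826 and 3.163).

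Other splits of the same libraries bear on each count of calls; 100 of 126 possible splits were drawn per comparison. For Vehicle versus Chow 1 split, the real one, reached 10035 genes (highest other 3801), and for SR9009 versus Chow 1 reached 10213 (highest other 7921). This is the smallest share that 100 splits can give, and it was not adjusted for the other split tests. It makes chance unlikely for both without excluding it. For SR9009 versus Vehicle 2 splits reached 44 genes, the real one included, a share under the threshold of 0.05. That share was not adjusted for the other split tests, so it makes chance unlikely without excluding it. The other split called 581 genes, many times the real count. It set Vehicle 1, 2 and 3 with SR9009 2 and 4, all with many receptor genes, against the remaining libraries, and points to a structure of the samples. It followed that class but for SR9009 5; the 3 other splits drawn that followed the class but for 1 library called 8, 1 and 0 genes. Within the classes, with 2 and 3 libraries per group, 10 and 21 genes were called for SR9009 versus Vehicle, and 78 with the class as a term. For opposite calls 2 splits reached 21 (highest other 43, the same split). For the numbers of lists called, 11 splits reached 30 lists for Vehicle versus Chow (highest other 32). For SR9009 versus Vehicle 32 reached 21 (highest other 27), and for SR9009 versus Chow 17 reached 29 (highest other 31). These counts cannot decide on chance. With these group sizes every other split leaves unequal shares of each group on either side, so it keeps part of the real difference. Camera with its preset correlation also called many lists where few genes were called: a Vehicle versus Chow split with 32 lists called 0 genes. No conclusion is drawn from the list counts. Chance cannot be excluded for the correlation of fold changes, where 77 splits lay as far from 0 (highest other 0.538).

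The first pattern weighed is the parting of the diet-fed libraries by receptor genes detected. Depth is argued against: with all libraries thinned to 29950509 counts, those with many kept at least 146 such genes, while diet-fed libraries with few had at most 71. An even background of reads over silent genes is argued against too, since the libraries with many had 3 to 6 of 141 keratin-associated, beta-defensin and bitter taste receptor genes, a range that overlaps the 4 to 8 of the diet-fed libraries with few. Other values differ between the classes: the imprinted noncoding genes Meg3, Rian and Mirg, chosen after their values were seen, were at 150, 79.9 and 4.86 CPM in diet-fed libraries with few and 38.5, 19.6 and 1.15 CPM in those with many, a choice that rules out a test, and the red cell, cholangiocyte, vascular endothelial, myofibroblast, fibrillar and remodelling scores differed by -1.52, -0.69, -0.44, -0.36, -0.47 and -0.43, few minus many (adjusted exact p = 0.0365 each). The source stays open, and no biological explanation was tested.

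The second pattern is the rise of drug metabolism genes. The receptor gene class is argued against, since the list score was at least 1.51 higher within each class. Misplaced Cyp2c29 reads are argued against for Cyp2c55, since the share its rise needs would give 23.8 CPM in Chow, above the highest Chow library (15.9 CPM). For Cyp2c37, Cyp2c50 (a call lost in 7 of 14 fits without 1 library) and Cyp2c54, the last also named after its values were seen, where up to 24.3% of Cyp2c29 reads would be needed, misplaced reads and separate rises cannot be told apart, because their Chow levels allow such shares. A hepatic response to the injected compound is a hypothesis that these data leave open.

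The third pattern is the shift of clock genes. The class is argued against here as well, with a score at least 0.27 higher in each class. A difference in the time of day at collection may give falls of Arntl and Npas2 with rises of Per3 and of Dbp (log2 fold change 1.69), as an agonist of REV-ERB may; the labels give no collection time, so the 2 cannot be told apart.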

How the results depend on the processing

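The alternatives on receptor gene classes, list scores, red cell and mesothelial terms, and leaving out libraries of the group a comparison does not use were chosen after seeing the data. For Vehicle versus Chow and SR9009 versus Chow, the numbers of genes called stayed within 1.5 times the reported counts under all alternatives run; with an estimated correlation the lists called were 1 in each. For SR9009 versus Vehicle, DESeq2 called 206 genes, the fit within few receptor genes 10, within many 21, with the class as a term 78, and leaving out 1 library gave 18 (without SR9009 replicate 4) to 56 (without Vehicle replicate 2). Lists called were 4 with an estimated correlation, 5 with fry, and 17 to 27 without 1 library. Opposite calls numbered 78 with DESeq2, 9 with split Vehicle libraries, and 10 to 23 without 1 library. The correlation was -0.312 with DESeq2, -0.208 to 0.0404 without 1 library, above 0 without Vehicle replicate 2 (0.0016) or SR9009 replicate 3 (0.0404), and 0.0085 with split Vehicle libraries. The cause of these changes was not tested.

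Replicate numbers name different mice. Of 13 same-numbered pairs, 3 correlated above 0.1 in their deviations (range -0.36 to 0.20), and 1 of 14 libraries correlated best with its own number, so the libraries share only a number. With the replicate block, 15 genes and 9 opposite calls were found for SR9009 versus Vehicle.

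For SR9009 versus Vehicle, these values or tests, among others, changed direction, with no call of any gene named here. With red cell and mesothelial terms, medians were -0.21 for fibrillar matrix and -0.29 for matrix remodelling. Log2 fold changes in that fit were -0.36 for Col1a1, -0.22 for Col3a1 and -0.0503 for Sparc. The mesothelial median there was 0.00087, with its test in the other direction and no call. That outcome was fixed in advance, because the mesothelial term is the score of the same list. Within few receptor genes, Col1a1 was at -0.44 and Col3a1 at -0.15; within many, Timp1 was at 0.18 and the sinusoidal endothelial median at -0.0473. Leaving out 1 library moved Col1a1 between -0.0752 and 0.24, Timp1 between -0.19 and 0.0934, and the pericentral median between -0.0308 and 0.24. Medians of lists not called also crossed 0: leaving out 1 library gave -0.0644 to 0.13 for matrix remodelling, -0.0582 to 0.16 for cell cycle and -0.0849 to 0.0203 for cytokines, and within few receptor genes the fibrillar median was -0.16 and the myofibroblast median -0.096. Against Chow, Cyp2c37 was at -0.003 within few receptor genes. The fibrillar list, not called with all libraries, was called higher without Vehicle replicate 2 or SR9009 replicate 3, at the preset correlation only. Depth was 29950509 counts or more, and the self-test recovered 39.3% of 1.5-fold changes for SR9009 versus Vehicle, so changes of that size can be missed.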

Other observations

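Other cell types differed between Vehicle and Chow livers. Of 23 T and NK cell markers 20 rose (camera adjusted p = 4.94e-05; adjusted p = 0.274 with an estimated correlation), and of 16 dendritic cell markers 12 rose (adjusted p = 2.77e-05; adjusted p = 0.203 with an estimated correlation). Interferon response genes had 20 of 26 members higher (adjusted p = 6.5e-06; adjusted p = 0.409 with an estimated correlation), and basement membrane genes 13 of 15 higher and 2 lower (adjusted p = 2.8e-05; adjusted p = 0.274 with an estimated correlation). Fetal and tumour-associated genes had 13 of 18 members higher (adjusted p = 0.000173; adjusted p = 0.216 with an estimated correlation). Periportal hepatocyte markers had 13 of 18 members lower and 2 higher (adjusted p = 0.000122; adjusted p = 0.311 with an estimated correlation), whereas pericentral markers were not called (6 higher, 4 lower of 18; adjusted p = 0.558). B and plasma cell markers were not called (adjusted p = 0.543), with 2 of 14 members lower, a median of -0.14 (0.22 without Chow replicate 4) and a mean of 0.17. Adjusted over the list alone, 22 T and NK cell, 13 dendritic, 20 interferon, 13 basement membrane and 15 fetal and tumour-associated genes rose and 13 periportal genes fell.

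Under SR9009, acute phase genes had a median log2 fold change of 0.33 against Vehicle (adjusted p = 0.00107; adjusted p = 0.606 with an estimated correlation). Red cell genes had a median of 1.12 (adjusted p = 0.0047, and 0.401 with an estimated correlation), which ran from 0.53 to 1.38 without 1 library. Their score differed by 0.73 (exact permutation p = 0.23). Periportal markers had a median of -0.15 (adjusted p = 0.00639, and 0.606 with an estimated correlation), which ran from -0.25 to -0.03 without 1 library. In these 3 lists edgeR called 0 of 23, 0 of 8 and 0 of 18 members; at an unadjusted p under 0.05, 3 acute phase and 1 red cell gene were higher and 4 periportal genes lower, and DESeq2 called 0, 0 and 1. The periportal call was lost without Vehicle replicate 2 or SR9009 replicate 1, 2 or 4 (adjusted p up to 0.212), and the red cell call without SR9009 replicate 5 (adjusted p = 0.069). Acute phase genes were not called within libraries with many receptor genes (adjusted p = 0.285) or with red cell and mesothelial terms (adjusted p = 0.127). Periportal markers were not called within libraries with few (adjusted p = 0.606). The acute phase score differed by 0.61 within few and 0.43 within many, about as much as the 0.50 across all. The periportal score differed by -0.11 and -0.25, against -0.20 across all. Cell cycle genes were not called (adjusted p = 0.571).

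Sinusoidal endothelial markers were called higher under SR9009 (median 0.20, 0 of 17 members called; adjusted p = 0.00318; adjusted p = 0.606 with an estimated correlation), but not without Vehicle replicate 5 (adjusted p = 0.214) nor with red cell and mesothelial terms (adjusted p = 0.158), and their median was -0.0473 within libraries with many receptor genes (adjusted p = 0.943). Interferon response genes were called higher (median 0.19, 0 of 26 members called; adjusted p = 0.00318; adjusted p = 0.662 with an estimated correlation), a call lost without Vehicle replicate 1, 2 or 3 or SR9009 replicate 1 (adjusted p up to 0.256). B and plasma cell markers were called lower (median -0.17, 0 of 14 members called, adjusted p = 0.0424, and 0.606 with an estimated correlation). Leaving out 1 library gave medians from -0.50 to -0.03, and the call was lost in 7 of 14 such fits (adjusted p up to 0.283). It was also lost without the low-count filter (adjusted p = 0.165) and with the receptor gene class as a term (adjusted p = 0.052). Within libraries with few receptor genes it was lost as well (adjusted p = 0.613).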
